A study of Mus musculus with 18 samples.

How the data were processed

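RNA was sequenced from alphaTC1 cells, a murine line of pancreatic alpha cells, in 2 experiments with 18 libraries. In experiment 1, cells carried an empty vector (EV, 3 libraries) or an shRNA against Smndc1 (shSmndc1, 3 libraries) and were taken 5 days after transduction. In experiment 2, cells also carried RIP-mCherry, a fluorescent reporter driven by the rat insulin promoter. Its groups were the empty vector (EV_RIP, 4 libraries) and cells with the shRNA sorted as reporter-negative (shSmndc1_RIP_neg, 4 libraries) or reporter-positive (shSmndc1_RIP_pos, 4 libraries). The labels give no day for experiment 2 and do not say whether the EV_RIP cells went through the sorter. Per the labels' protocols, RNA was extracted with a column kit with DNase treatment, and stranded mRNA libraries were read as 75 bp paired ends.

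The authors deposited, for each experiment, a table of raw counts per Ensembl gene with 1 column per library, and the count values are whole numbers with no scaling. The deposited FPKM tables hold the same counts divided by gene length and by median-of-ratios size factors, as shown by recomputing the factors from the deposited counts with DESeq2. The ratios of FPKM to counts differed from those factors by at most 2.2e-16 over the 13267 and 11071 genes checked. Per the submitters' processing notes, STAR 2.7.5a, Picard 2.19.2 and DESeq2 1.30.0 were used with the GRCm38/mm10 build. The role of each tool, the program that counted the reads and its strand setting are not given in the sources used here. Each table lists 55487 genes by identifier and symbol, and their positions and biotypes are the deposited ones. Of these genes 54821 have identical coordinates in the GENCODE annotation of GRCm38 that was used here for introns and exon overlaps.

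Counting appears blind to strand: 283 genes have over 90% of their exonic bases on the opposite strand of a gene with at least 1000 counts, and 267 of them hold at least 10 counts, with a median of 0.0746 of the partner's count and 0.0564 of its length. Reads from a gene and an overlapping partner cannot then be told apart. Shares of exonic bases on the other strand of a partner were 73.5% for Mt2, 67.3% for Gins2, 52.3% for Wdr83os, 22.9% for Fam83f, 20.7% for Ptbp1 and Cebpb, 15.9% for Ghrl, 15.1% for Csf1r and 12.5% for Ccna2. On the same strand, Fdps shared 26.7%, Snhg12 25.2%, Spp1 18.8%, Zfas1 15.7%, Snhg8 15.2% and Tm7sf2 12.1%. Ddit3 shared 6.13% on the same and 4.73% on the other strand. Values of these genes are uncertain to that extent, as are those of families of near-identical genes (Zscan4, Usp17l, Tcstv, Hspa1a with Hspa1b, Ins1 with Ins2). Whether the reporter's transcript holds insulin sequence that would count toward Ins1 or Ins2 cannot be read from the tables. Ins2 shares no exonic base with another gene.

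All further steps were done here in R 4.3.3. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 6 libraries of experiment 1 made one fit, and the 12 of experiment 2 another, so that its 3 contrasts share one estimate of the spread. The difference between the effect of experiment 1 and that of experiment 2, taken as the mean of negative and positive cells against EV_RIP, was tested as an interaction in a fit over all 18 libraries. Levels are given as CPM, counts scaled to TMM-scaled library sizes, as mean ± SD. The labels do not say that replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical. Intervals for counts of 0 take 3 counts as the upper limit and cover counting error only. A log2 fold change of a gene with a few counts depends on the prior count of the fit.

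Genes named in the text follow a rule: Smndc1, Ins1, Ins2, Gcg, Pdx1, Mafa and Atrx wherever tested; per comparison the 10 higher and 10 lower genes with the largest fold change among those past the threshold, with a mean of at least 5 CPM, no overlap of the 2 groups and a symbol that is not a predicted gene; up to 4 members per gene list with the smallest p; and the 5 genes with the smallest p for the difference between experiments. In the paired fit, the same direction in 4 of 4 pairs took the place of no overlap. Some further genes of the rule are not reported here. Genes singled out beyond this rule are named as such. The rule, the groups, the tests, the gene lists and most alternatives were fixed before the data were examined.

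The 25 gene lists were alpha cell identity; beta cell identity; delta, PP and epsilon cell markers; pan-endocrine transcription factors; secretory granule and exocytosis genes; genes repressed in beta cells; chromatin remodelling factors; U2 and tri-snRNP spliceosome factors; the SMN complex; SR and hnRNP splicing regulators; snoRNA host genes; p53 targets; the ATF4 and CHOP integrated stress response; ER chaperones; G2 and M phase genes; G1/S and DNA replication genes; interferon-stimulated genes; immediate-early genes; cytosolic heat shock proteins; cholesterol synthesis; mitochondrial transcripts; and markers of fibroblasts, leukocytes and macrophages, acinar and duct cells, and endothelium. Lists were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, then with an estimated correlation, and by the self-contained test fry.

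Each step was tested on counts simulated from the real means and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. For experiment 1 (17905 genes), 75% and 97% were recovered and 4.44% of the calls were false. For negative cells (18546 genes) these values were 67%, 94% and 4.73%, for positive cells (18577 genes) 68%, 100% and 4%, and for positive against negative cells (18547 genes) 74%, 96% and 5.56%. With simulated shifts between pairs of a chosen size (17632 genes), the paired fit recovered 67% and 94% with 5.85% false calls, and the unpaired fit on the same counts recovered 0% and 56%. The shifts were added to a spread estimated without pairing, so the loss in the unpaired fit was built in. It does not tell how much the real unpaired fit missed. All 24 pairs of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom between 13.5 and 203.

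Whether replicate numbers pair the libraries was checked by correlating their deviations from the group means across genes. Negative and positive libraries of the same number correlated at 0.62, 0.35, 0.14 and 0.31, each the highest for its number, so the numbers pair the sorted groups. A fit of these 8 libraries with the replicate number as a block was therefore set beside that comparison. The alternatives were the size factors of DESeq2 1.42.0, scaling without the 10 most abundant genes, other filters (at least 1 count, or a mean of 1 CPM), the DESeq2 Wald test, a minimum fold of 2, the replicate block, limma on log2(FPKM + 1), only the 2 compared groups and leaving out each library. Thinning to the shallowest library, the block over the sorted libraries alone, with and without pair 3, and leaving out negative libraries 3 and 4 were added after seeing the data. FPKM were not compared across experiments, because the tables were normalized apart.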

Results

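The series asks how loss of Smndc1, a splicing factor, changes alpha cells, and whether a subpopulation of them turns on insulin. Its 18 libraries form 5 groups: EV and shSmndc1 with 3 libraries each in experiment 1, and EV_RIP, shSmndc1_RIP_neg (negative cells) and shSmndc1_RIP_pos (positive cells) with 4 each in experiment 2. Total counts lay between 40782000 and 53455000 in EV, 37233000 and 66676000 in shSmndc1, 49345000 and 103050000 in EV_RIP, and 34045000 and 48139000 in positive cells. Negative libraries were less even, at 38870000, 80757000, 8084600 and 23744000 for replicates 1 to 4. Negative replicates 2, 3 and 4 also carried more Rn7sk, an RNA without a poly(A) tail, with 19.4, 166 and 48.1 CPM, against 2.41 to 4.79 CPM in positive cells and 5.18 to 13.8 CPM in EV_RIP. Negative replicate 1, with 4.45 CPM, lay within the range of positive cells. Histone transcripts stood at 7.13 ± 4.08 CPM (SD, n = 4) in negative cells, 3.64 ± 1.76 CPM in positive cells and 3.26 ± 1.23 CPM in EV_RIP. Mitochondrial transcripts took 0.587% of the counts in EV_RIP replicate 1 and between 2.34% and 4.60% in the other libraries of experiment 2. In experiment 1, shSmndc1 replicate 3 stood apart, with 9.35 CPM of Rn7sk (2.56 to 4.29 in the other 5 libraries) and 5.51 CPM of histone transcripts (2.67 to 3.03). Mitochondrial transcripts took 4.76% of its counts (2.44% to 3.20%), and Malat1, a nuclear RNA, had 1147 CPM (171 to 477).

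Smndc1 (ENSMUSG00000025024, chromosome 19, 53379390 to 53390578, GRCm38) was first read in every library. It had 41.9, 40.2 and 35.1 CPM in EV and 10.4, 9.52 and 10.5 CPM in shSmndc1. In experiment 2 it had 37.6, 54.9, 39.3 and 46.3 CPM in EV_RIP, 16.6, 22.4, 16.0 and 25.2 CPM in positive cells, and 23.9, 43.4, 36.3 and 44.6 CPM in negative cells. Against its own control, Smndc1 fell by 1.94 on the log2 scale in shSmndc1 (SE 0.13, edgeR adjusted p = 0.00145) and by a log2 fold change of -1.15 in positive cells (SE 0.20, edgeR adjusted p = 0.00384). In negative cells the log2 fold change was -0.27 (SE 0.20, edgeR adjusted p = 0.378), which did not pass.

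**Figure D1:**
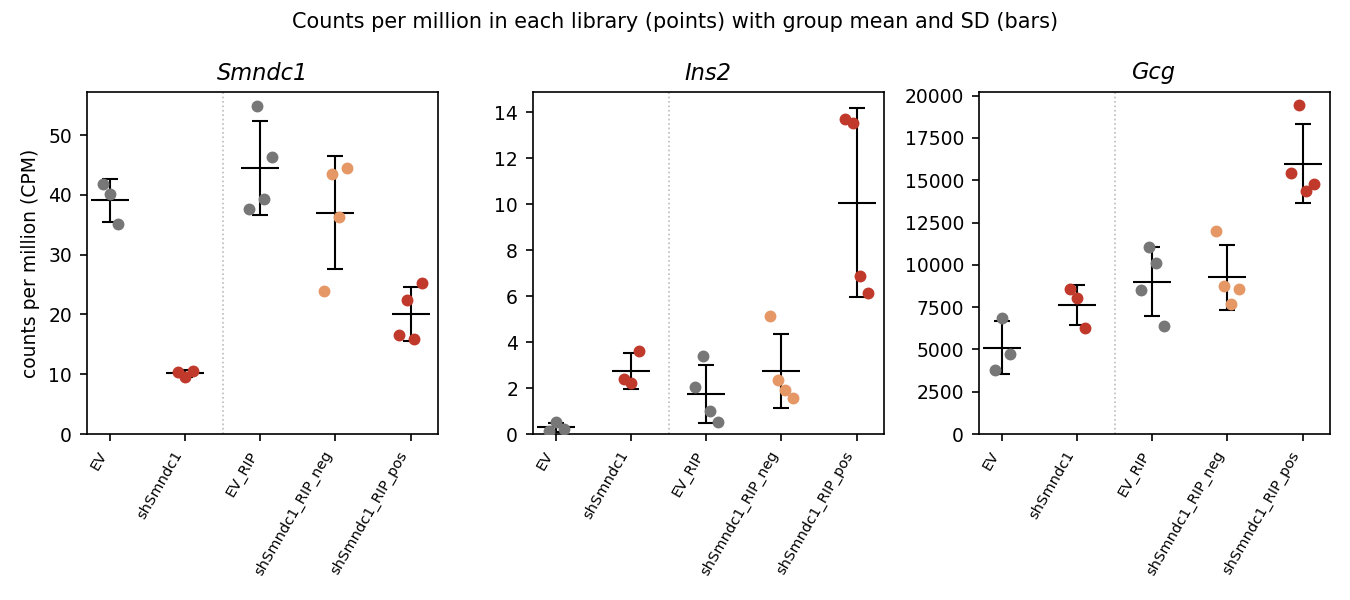
Expression of Smndc1, Ins2 and Gcg in CPM for each library (points) of the 5 groups, with mean and SD as bars. Ins2 reaches 13.7 CPM in positive cells, while no negative library exceeds 5.13 CPM.

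The first comparison, shSmndc1 against EV, asks what the knockdown does 5 days after transduction. Insulin transcripts rose from a very low level. Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) went from 0.286 ± 0.198 CPM to 2.74 ± 0.771 CPM (SD, n = 3), a log2 fold change of 3.21 (SE 0.47, edgeR adjusted p = 0.0075). Mafa, a transcription factor of mature beta cells, rose from 1.13 ± 0.281 CPM to 2.86 ± 0.506 CPM, a log2 fold change of 1.35 (edgeR adjusted p = 0.0185). Atrx, a chromatin remodeller, fell from 268 ± 4.95 CPM to 198 ± 15.8 CPM, a log2 fold change of -0.44 (SE 0.12, edgeR adjusted p = 0.0374).

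The glucagon gene Gcg (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650) stood at 5114 ± 1578 CPM in EV and 7631 ± 1189 CPM in shSmndc1, and its log2 fold change of 0.58 (SE 0.24) did not pass (edgeR adjusted p = 0.136). Ins1 had 0 counts in the 3 EV libraries, which allows up to 0.0737 CPM in the shallowest, and 0, 2 and 26 counts in the knockdown, too few to be tested. Pdx1 had 1 count in the whole experiment. Several calls were lost with fewer libraries, at similar fold changes. Without EV replicate 3, Ins2 (log2 fold change 3.06, edgeR adjusted p = 0.0556) no longer passed. Mafa missed the threshold without EV replicate 2 (1.26, 0.0731), EV replicate 3 (1.23, 0.0938) or shSmndc1 replicate 2 (1.36, 0.0641), and Atrx without any library except shSmndc1 replicate 3 (log2 fold changes of -0.46 to -0.41, adjusted p between 0.0703 and 0.158).

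Of 18202 genes tested with edgeR, 1315 were higher and 1366 lower in shSmndc1, and over all tested genes the groups did not overlap in 39.5%, where chance gives 10%. The counts were 249 and 301 without EV replicate 2, 71 and 110 without EV replicate 3, and 337 and 290 without shSmndc1 replicate 2. By the rule for naming genes, the largest rise was in Egr1, an immediate-early transcription factor, from 2.57 ± 0.420 to 38.2 ± 27.4 CPM (log2 fold change 3.90, SE 0.47, adjusted p = 0.00536). Csf1, which encodes macrophage colony-stimulating factor (3.04, SE 0.69, 0.0242), and Junb, a subunit of AP-1, from 8.56 ± 1.78 to 50.7 ± 54.3 CPM (2.56, SE 0.65, 0.0336), rose next to it. Eno3, the muscle enolase, rose from 4.35 ± 0.683 to 19.0 ± 3.38 CPM (2.13, SE 0.19, 0.00263), and Pianp from 3.55 ± 0.0769 to 14.1 ± 2.51 CPM (1.99, SE 0.18, 0.00263). Fam129b, Fndc4, Wfikkn1, Prr7 and Nol4l rose by log2 fold changes of 2.86, 2.25, 2.15, 1.96 and 1.96. The deepest falls besides Smndc1 were in Akr1c14, a hydroxysteroid dehydrogenase (-2.77, SE 0.42, 0.00836), Nptx1, neuronal pentraxin 1 (-2.52, SE 0.32, 0.00606), and Msn, which links the membrane to actin, from 320 ± 32.3 to 62.1 ± 34.4 CPM (-2.36, SE 0.38, 0.00891). Wdr83os (-2.30), the liver glycogen synthase Gys2 (-2.17), the apolipoprotein Apof (-2.17), the exocytosis protein Rph3a (-2.09), Elfn2 (-1.89) and the glycolytic enzyme Pgam1, from 216 ± 26.7 to 60.4 ± 12.8 CPM (-1.84), fell as well. Of the 66 named genes that passed in this comparison, 52 missed the threshold without EV replicate 3, 37 without EV replicate 2, and 33 without shSmndc1 replicate 2. The tally was 16 without EV replicate 1, 9 without shSmndc1 replicate 1 and 4 without shSmndc1 replicate 3, and none changed sign.

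Camera called 0 of the 25 gene lists in this comparison (5 at an unadjusted p under 0.05), also with an estimated correlation (smallest adjusted p = 0.967, 0 at an unadjusted p under 0.05). Fry called 1, the fibroblast markers (fry adjusted p = 0.0161), whose only called member of 5 was the collagen gene Col6a1 (2.47). Single members changed. Of 25 secretory granule and exocytosis genes, 4 fell (4 adjusted over the list alone, camera adjusted p = 0.182). These were Ptprn, a protein of the dense-core granule membrane, from 1406 to 544 CPM (-1.37, edgeR adjusted p = 0.0088), the SNARE protein Snap25 (-0.86), Scg5 (-0.83) and chromogranin A, Chga (-0.63). Of 12 alpha cell genes, 1 rose and 1 fell, the prohormone convertase Pcsk2 (-0.94, edgeR adjusted p = 0.0359), with the same counts adjusted over the list alone (camera adjusted p = 0.594). Of 13 beta cell genes, 2 rose (Ins2, Mafa) and 3 fell, among them the prolactin receptor Prlr (-1.36) and the zinc transporter Slc30a8 (-0.72), with 2 and 4 adjusted over the list alone (camera adjusted p = 0.925). Of 11 pan-endocrine factors, Foxa1 rose (1.67), and Nkx2-2 (-0.71) and Foxa2 (-0.55) fell, also adjusted over the list alone (camera adjusted p = 0.489). Of 10 genes repressed in beta cells, Pdgfra (1.57) and Slc16a1 (0.47) rose and Igfbp4 (-1.79) and Lmo4 (-0.71) fell, also adjusted over the list alone (camera adjusted p = 0.882). None of 3 delta, PP and epsilon cell markers changed (camera adjusted p = 0.594).

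Splicing and chromatin genes changed in both directions. Of 35 chromatin remodelling factors, 2 rose, among them Smarcd2 (1.09, edgeR adjusted p = 0.00822), and 4 fell, among them Smarcc1 (-1.01), Smarca2 (-0.72) and the DNA methyltransferase Dnmt3a (-0.71), with 3 and 5 adjusted over the list alone (camera adjusted p = 0.643). Of 35 U2 and tri-snRNP factors, Prpf3 (0.76), Prpf8 (0.55) and Cdc40 (0.44) rose, also adjusted over the list alone (camera adjusted p = 0.489). Of 13 SMN complex genes, Coil rose (0.41; 0 adjusted over the list alone, camera adjusted p = 0.771). Of 35 SR and hnRNP regulators, Ptbp1, known to repress production of its paralog Ptbp2, fell from 266 ± 37.7 to 129 ± 25.8 CPM (-1.05, edgeR adjusted p = 0.0111). Hnrnph1 fell (-0.63) and Ptbp2 rose (0.49, edgeR adjusted p = 0.0419), with 1 lower adjusted over the list alone (camera adjusted p = 0.643). The snoRNA host genes had 0 calls of 12 (camera adjusted p = 0.594).

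Few stress and proliferation genes changed. Of 20 immediate-early genes, Egr1, Junb and Egr2 (1.44) rose, also adjusted over the list alone (camera adjusted p = 0.108). Adjusted over the list alone, counts were 0 for p53 targets (1 of 22 higher over all genes, Gtse1 0.74; camera adjusted p = 0.226), the integrated stress response (2 of 19 lower, Psat1 -0.91 and Slc7a5 -0.88; 0.190), G2 and M phase genes (1 of 24 lower, Ccnb2 -0.68; 0.643) and G1/S genes (2 of 24 higher, Gins2 0.56 and Slbp 0.44; 0.882). Creld2 (0.80) rose among 22 ER chaperones (0.643), Bag3 (0.70) among 14 heat shock genes (0.534), and Hsd17b7 (-1.57) fell among 20 cholesterol genes (0.190), each the 1 call adjusted over the list alone. Cxcl10 (4.30) and Parp14 (2.15) rose among 14 interferon genes, with 2 higher and 2 lower adjusted over the list alone (0.594). None of 13 mitochondrial transcripts passed (0.957). Of the markers of other cell types, Csf1r (0.60) rose among 3 leukocyte markers (2 adjusted over the list alone, 0.437), Cel (3.66) and Spp1 (1.87) among 8 acinar and duct markers (3 higher and 1 lower, 0.274), and Esam (2.21) among 5 endothelial markers (1, 0.771). The median and the direction of camera differed in sign for the lists of genes repressed in beta cells, of G1/S genes and of endothelial markers. Camera called 3 lists without EV replicate 1, 3 without EV replicate 3, 4 without shSmndc1 replicate 1 and 1 without shSmndc1 replicate 2, immediate-early genes in the last 3 of these settings.

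The comparison of negative cells with EV_RIP asks what sorted cells without reporter signal express. Smndc1 did not pass in it, so a knockdown is not shown in these libraries. Ins2 (1.74 ± 1.27 CPM in EV_RIP, 2.74 ± 1.62 CPM in negative cells, SD, n = 4), Gcg (9009 ± 2039 and 9254 ± 1906 CPM), Mafa and Atrx had log2 fold changes of 0.67, 0.04, 0.30 and -0.07, and none passed (edgeR adjusted p between 0.371 and 0.902). Ins1 had 9 counts in EV_RIP and 52 in negative cells, and its log2 fold change of 3.25 (SE 1.19, edgeR adjusted p = 0.0771) passed without negative replicate 1 (3.71, 0.0181). Of 18897 genes tested with edgeR, 1544 were higher and 1076 lower, and over all tested genes the groups did not overlap in 14.4%, where chance gives 2.86%. By the same rule, the largest rises were in the AP-1 genes Fosb (log2 fold change 3.71, SE 0.73, adjusted p = 0.0124), Fos, from 14.1 ± 6.58 to 109.6 ± 47.9 CPM (2.96, SE 0.55, 0.0112), and Junb (2.39). Others were in Egr1 (3.14, SE 0.30, 0.000616), Atf3 (2.42, SE 0.41, 0.00844), Myc (2.45), Zfp750 (2.91) and the metallothionein Mt2 (2.65). The clock repressors Nr1d1, from 72.8 ± 29.5 to 413 ± 222 CPM (2.50, SE 0.39, 0.0074), and Ciart (2.39) rose with them. The deepest falls were in Apof (-1.83, SE 0.37, 0.0134), Nptx1 (-1.42, SE 0.29, 0.0136), Spink4 (-1.37), Btbd17 (-1.35), the gap junction gene Gjd2 (-1.34), Tm7sf2 (-1.34), Fam83f (-1.34), Hsbp1l1 (-1.28), Hsd11b1, which activates glucocorticoids (-1.27), and Akr1c14 (-1.26).

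Camera with its preset correlation called 6 lists higher in negative cells. Fry called 5 of them, without the ER chaperones (fry adjusted p = 0.0828). Of 23 p53 targets, 13 rose (16 adjusted over the list alone), with a median log2 fold change of 0.96 (camera adjusted p = 1.06e-09; adjusted p = 0.328 with an estimated correlation). They included Mdm2, the ubiquitin ligase of p53, from 119 ± 28.3 to 432 ± 196 CPM (1.86, SE 0.32, edgeR adjusted p = 0.00938), the cell death gene Bbc3 (1.75), Gtse1 (1.18) and Btg2 (0.72). Of 21 immediate-early genes, 8 rose (11 adjusted over the list alone), Jun (1.95) and Zfp36 (1.75) among them (camera adjusted p = 2.37e-09; adjusted p = 0.328 with an estimated correlation). Of 12 snoRNA host genes, whose spliced RNAs are substrates of decay, 8 rose (9 adjusted over the list alone), led by Snhg15 (2.35, to 146 ± 72.7 CPM), Snhg12 (1.80), Zfas1 (1.54) and Snhg17, with camera adjusted p = 2.83e-07 and adjusted p = 0.328 with an estimated correlation. Of 14 heat shock genes, 6 rose (10 adjusted over the list alone), among them Hspa1b (3.89), Hsph1 (1.17), Dnajb1 (0.89) and Bag3 (0.87), with camera adjusted p = 5.51e-05 and adjusted p = 0.328 with an estimated correlation. Of 15 interferon genes, 5 rose (7 adjusted over the list alone), such as Mx2 (1.89) and Rsad2 (1.16), and of 22 ER chaperones 3 (3 adjusted over the list alone), Hspa5 (0.88), Dnajb9 (1.05) and Creld2 (0.72). Camera adjusted p was 0.0203 for both, and adjusted p = 0.328 and 0.660 with an estimated correlation. Rn7sk and histone transcripts, signs of RNA without a poly(A) tail, were highest in negative replicates 3 and 4, at 166 and 48.1 CPM for Rn7sk and 10.4 and 10.7 CPM for histones. With those libraries left out, an alternative chosen after seeing the data, camera adjusted p was 3.31e-10 for p53 targets, 3.47e-08 for immediate-early genes, 5.24e-06 for snoRNA hosts, 0.0156 for heat shock genes, 9.87e-04 for interferon genes and 0.535 for ER chaperones. The ER chaperones were also lost without EV_RIP replicate 2 (camera adjusted p = 0.0725), EV_RIP replicate 3 (0.0592) or negative replicate 3 (0.243). The interferon and ER chaperone lists both lost their call with the replicate block over all libraries of experiment 2. The labels do not say whether EV_RIP cells were sorted, and immediate-early genes also respond to cell dissociation.

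Some mitotic and granule genes fell in the same cells. Of 24 G2 and M phase genes, 9 fell (12 adjusted over the list alone), among them the kinase Cdk1, from 329 ± 22.9 to 199.8 ± 58.6 CPM (-0.72, edgeR adjusted p = 0.0178), Ccnb2 (-0.97), Aurkb (-0.53) and Birc5 (-0.50), with camera adjusted p = 1.22e-05 and adjusted p = 0.328 with an estimated correlation. Of 25 granule and exocytosis genes, 6 fell (8 adjusted over the list alone), with Ptprn (-0.95), Scg5 (-0.96), Snap25 (-0.77) and Chga (-0.65) named again, and camera adjusted p = 2.46e-04 and adjusted p = 0.328 with an estimated correlation. Camera did not call the other 17 lists (adjusted p between 0.0662 and 0.863), of which fry called pan-endocrine factors (0.0362), leukocyte markers (0.0174) and endothelial markers (0.0174). Among them, Pcsk2 fell of 13 alpha cell genes (-0.96, 1 adjusted over the list alone), and Slc30a8 (-0.89), G6pc2 (-1.08) and Prlr (-0.99) of 14 beta cell genes (3 adjusted over the list alone). Of 19 integrated stress response genes, Ddit3, which encodes CHOP (2.08), and Trib3 (1.22) rose (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.572). Of 35 chromatin factors, 7 rose, such as Kmt2d (0.89) and Kmt2a (0.65), and 2 fell (7 and 3 adjusted over the list alone). Of 35 U2 and tri-snRNP factors 3 rose, such as Prpf8 (0.59; 3 adjusted over the list alone), and 5 of 35 SR and hnRNP regulators rose, such as Srrm1 (0.66; 10 higher and 1 lower adjusted over the list alone). Of 5 endothelial markers, Esam (3.02), Pecam1 (1.61) and Tek (2.05) rose (3 adjusted over the list alone, camera adjusted p = 0.0662), to at most 3.25 ± 1.23 CPM. Camera called this list without EV_RIP replicate 1 (0.0484) or negative replicate 2 (0.0373).

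Calls in the negative comparison changed with the libraries used. Without negative replicate 4, edgeR called 127 genes higher and 32 lower, and without negative replicate 2 it called 304 and 88. The counts were 771 and 323 without negative replicate 3, and without EV_RIP replicate 1 or 3 they were 359 and 180 or 654 and 468. Without negative replicate 1 they grew to 3036 and 2795. Of the 78 named genes that passed, 56 were lost without negative replicate 4, 41 without negative 2, and 36 without EV_RIP 1. Fewer were lost in the other settings, 21 without negative 3, 20 without EV_RIP 3, 12 without EV_RIP 4, 6 without EV_RIP 2 and 0 without negative 1. With negative replicates 3 and 4 both left out, chosen after seeing the data, 4 genes were higher and 0 lower at the threshold. Log2 fold changes were then 3.59 for Fosb, 1.53 for Mdm2, -1.73 for Apof and -1.43 for Nptx1, near those with all libraries, but 1.02 for Hspa1b and 0.42 for Trib3, against 3.89 and 1.22 with all.

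The comparison of positive cells with EV_RIP asks what the cells that turned on the insulin reporter express. The sort picked these cells by activity of an insulin promoter, and no group of reporter-positive cells with the empty vector exists. Higher insulin transcripts may therefore come from the selection and cannot be read as an effect of the knockdown alone. Ins2 rose from 1.74 ± 1.27 to 10.1 ± 4.12 CPM (SD, n = 4), a log2 fold change of 2.51 (SE 0.51, edgeR adjusted p = 0.00701). Ins1 rose from 0.0292 ± 0.0262 to 0.938 ± 0.930 CPM (4.72, SE 1.13, edgeR adjusted p = 0.0142). The glucagon gene rose too: Gcg went from 9009 ± 2039 to 15987 ± 2329 CPM (0.83, SE 0.18, edgeR adjusted p = 0.00978), and stayed far above the insulin genes in CPM. Mafa rose from 1.16 ± 0.214 to 2.49 ± 0.687 CPM (1.09, edgeR adjusted p = 0.0125). Atrx had a log2 fold change of -0.23 (edgeR adjusted p = 0.371), and Pdx1 had 1 count in the whole experiment. On the log2(FPKM + 1) scale, limma gave adjusted p = 0.144 for Gcg and 0.0770 for Ins1.

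Of 18897 genes tested with edgeR, 1600 were higher and 1686 lower in positive cells, and over all tested genes the groups did not overlap in 23.4%, where chance gives 2.86%. Of the genes named by size, Egr1 rose most, from 2.32 ± 0.544 to 40.6 ± 13.7 CPM (log2 fold change 4.13, SE 0.31, adjusted p = 2.45e-05). Next were Fosb (3.31, SE 0.72, 0.00928) and osteopontin, Spp1, a secreted protein, from 6.26 ± 3.79 to 43.0 ± 19.7 CPM (2.77, SE 0.49, 0.00361). Csf1 (2.03), Begain (2.02, SE 0.26, 0.000947), the mRNA decay factor Zfp36 (2.00), Ciart (1.94), Pianp (1.82) and Frat2 (1.80) rose as well. Nptx1 (-2.15, SE 0.30, 0.00134), Apof (-2.10), Igfbp4, which binds insulin-like growth factors, from 202 ± 89.7 to 48.5 ± 28.8 CPM (-2.05, SE 0.48, 0.0132), Lsamp (-2.04), Ppp2r2b (-1.90) and Elfn2 (-1.89) fell most. Msn, from 312 ± 46.5 to 91.8 ± 28.6 CPM (-1.77, SE 0.19, 0.000295), the receptor Gpr142 (-1.77), Rph3a (-1.64) and Gmds (-1.62) fell too. Of the 76 named genes that passed, 23 were lost without positive replicate 2, 21 without EV_RIP 1, 17 without EV_RIP 3, 17 without positive 4, 16 without positive 3, 12 without EV_RIP 4, 5 without positive 1 and 1 without EV_RIP 2. The counts of genes higher and lower were 755 and 810 without EV_RIP replicate 1, 889 and 979 without EV_RIP 3, 646 and 612 without positive 2, 1009 and 1064 without positive 3, and 962 and 967 without positive 4.

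In positive cells camera with its preset correlation called 2 lists lower, granule and cholesterol genes, and 3 higher, snoRNA hosts, immediate-early and interferon genes. Fry called only the interferon list (0.00391), with adjusted p = 0.117 for granule, 0.189 for cholesterol and 0.101 for snoRNA host and immediate-early genes. Of 25 granule genes, 5 fell (5 adjusted over the list alone), Ptprn (-1.22, edgeR adjusted p = 0.00289), Scg5 (-1.24), Chga (-0.67) and Ptprn2 (-0.99) among them, with camera adjusted p = 0.00651 and adjusted p = 0.759 with an estimated correlation. Of 20 cholesterol synthesis genes, 4 fell (8 adjusted over the list alone), Hsd17b7 (-0.91), Fdps (-0.68), Dhcr7 (-0.49) and Sqle (-0.40), with camera adjusted p = 0.00671 and adjusted p = 0.821 with an estimated correlation. The list was not called without EV_RIP replicate 1 (camera adjusted p = 0.0751). Of 12 snoRNA hosts, 6 rose (8 adjusted over the list alone), Snhg12 (1.51), Zfas1 (1.42), Snhg17 (0.95) and Snhg8 (0.76) among them, with camera adjusted p = 1.60e-04 and adjusted p = 0.759 with an estimated correlation. Of 21 immediate-early genes, 7 rose (10 adjusted over the list alone), with Fos (2.60) and Junb (1.78) beside Egr1, and camera adjusted p = 2.05e-04 and adjusted p = 0.759 with an estimated correlation. Of 15 interferon genes, 6 rose (8 higher and 1 lower adjusted over the list alone), such as Cxcl10 (3.07), Parp14 (2.49), Ddx58 and Rsad2 (1.25), with camera adjusted p = 0.00455 and adjusted p = 0.613 with an estimated correlation. The other 20 lists were not called (camera adjusted p between 0.198 and 0.981). Of 23 p53 targets, 0 passed (0 adjusted over the list alone, camera adjusted p = 0.419), with a median log2 fold change of 0.19. Of 14 heat shock genes, Bag3 rose (0.80) and Hspa8 fell (-0.36), also adjusted over the list alone (camera adjusted p = 0.831).

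Single identity, splicing and chromatin genes changed in positive cells, though their lists were not called. Of 13 alpha cell genes, 4 rose, Gcg and Fap (1.78) among them, and Pcsk2 fell (-1.17, edgeR adjusted p = 0.00382), also adjusted over the list alone (camera adjusted p = 0.215). Of 14 beta cell genes, 4 rose, Ins1, Ins2, Mafa and the islet amyloid gene Iapp, from 0.189 ± 0.129 to 0.917 ± 0.304 CPM (2.23, edgeR adjusted p = 0.0326), and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.264). Of 35 chromatin factors, 4 rose, such as Chd3 (2.29) and Kmt2d (0.62), and 4 fell, such as Smarcc1 (-0.75) and Dnmt3a (-0.61), with 7 and 4 adjusted over the list alone (camera adjusted p = 0.555). Of 35 U2 and tri-snRNP factors, 4 rose, such as Prpf8 (0.66) and Snrnp200 (0.50), and 2 fell, also adjusted over the list alone (camera adjusted p = 0.280). Of 35 SR and hnRNP regulators, 6 rose, such as Srrm2 (0.56), and 2 fell, Ptbp1 (-0.68, edgeR adjusted p = 0.0084) and Rbfox2 (-0.42), with 8 and 2 adjusted over the list alone (camera adjusted p = 0.264).

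**Figure D2:**
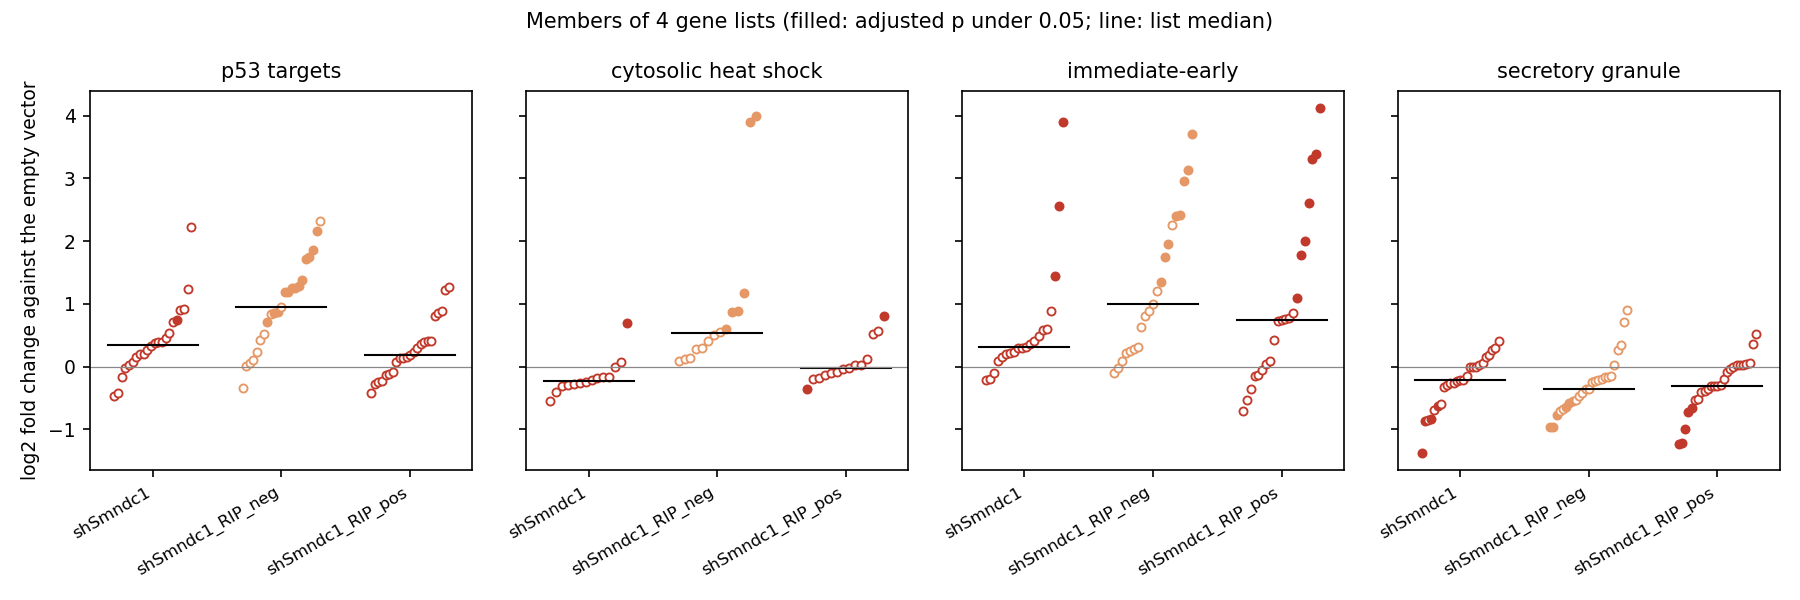
Log2 fold change against the matching empty vector of each member of the p53, heat shock, immediate-early and secretory granule lists in shSmndc1, negative and positive cells (filled points passed the edgeR test, lines are medians). The p53 median is 0.96 in negative cells and 0.19 in positive cells.

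The comparison of positive with negative cells sets the subpopulation that induced the reporter against the one that did not. The insulin reporter itself divided these cells, so a difference in insulin transcripts is what the sort selects for. With the replicate number as a block over the 8 sorted libraries, positive cells had more insulin and glucagon transcripts and less Smndc1. Ins2 rose from 2.79 ± 1.65 to 10.2 ± 4.17 CPM (SD, n = 4; log2 difference 1.95, SE 0.20, edgeR adjusted p = 1.41e-04). Gcg rose from 9416 ± 1953 to 16281 ± 2399.6 CPM (0.80, SE 0.13, edgeR adjusted p = 0.00223) and Ins1 from 0.312 ± 0.420 to 0.956 ± 0.949 CPM (1.81, SE 0.46, edgeR adjusted p = 0.0266), each in 4 of 4 pairs. Smndc1 was lower by a log2 difference of -0.86 (SE 0.12, edgeR adjusted p = 9.54e-04) in 4 of 4 pairs. Mafa (0.71, edgeR adjusted p = 0.0920) and Atrx (-0.19, 0.360) did not pass. In the fit without the block, planned as the first, none of these genes passed. Log2 differences were 1.84 for Ins2 (edgeR adjusted p = 0.184), 0.79 for Gcg (0.127), 1.47 for Ins1 (0.548) and -0.89 for Smndc1 (SE 0.21, 0.127). Without negative replicate 1 that fit called Ins2 (2.36, 0.0356), Gcg (0.95, 0.0189) and Smndc1 (-1.04, 0.0122). Under other choices made in advance, Ins2 passed with the block over 12 libraries (1.92, 0.0438) and without a filter (1.85, 0.0172), and Gcg by DESeq2 (0.80, 0.00715) and without a filter (0.80, 0.0287).

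The number of genes called also depended on the block. Without the block, edgeR called 0 of 18897 genes, with 2314 at an unadjusted p under 0.05 and a smallest adjusted p of 0.127, while DESeq2 called 110 higher and 205 lower and limma on log2(FPKM + 1) called 0. With the block, edgeR called 667 genes higher and 850 lower of 17994. Without the block and without negative replicate 1, it called 220 and 297. Besides Ins2, the largest rises by that rule in the blocked fit were in Spp1, from 13.6 ± 6.40 to 43.8 ± 20.2 CPM (1.68, SE 0.19, edgeR adjusted p = 3.04e-04), Speg (1.66), Islr (1.65) and the water channel Aqp1 (SE 0.20, 0.00102). Then came Hapln1 (1.47), Vstm2l (1.43), Car13 (1.35), the guidance cue Sema3a (1.31) and Klhl4 (1.26). The deepest falls were in the inducible heat shock genes Hspa1a (-3.12, SE 0.29, 6.90e-05) and Hspa1b, from 24.7 ± 34.0 to 2.33 ± 2.21 CPM (-2.93, SE 0.24, 3.04e-05), and in Rn7sk, from 58.3 ± 72.3 to 3.81 ± 1.06 CPM (-3.05, SE 0.45, 0.00137). They were followed by Adam8 (-1.66), Zfp750 (-1.65), the stress factor Atf3, from 81.5 ± 39.5 to 25.2 ± 12.4 CPM (-1.62, SE 0.14, 4.13e-05), Mctp2, Atg9b (-1.43), Lsamp (-1.42) and Ppp2r2b (-1.42). Each of these genes moved the same way in 4 of 4 pairs.

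In the blocked fit camera with its preset correlation called p53 targets and heat shock genes lower in positive cells, and alpha cell genes (7 of 13 members) and beta cell genes (5 of 12) higher. For all 4 lists adjusted p = 0.254 with an estimated correlation, and fry gave 0.104 for p53 targets and 0.0762 for the other 3. Of 22 p53 targets, 14 were lower and Sesn1 higher in the blocked fit (19 and 1 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 1.21e-17; adjusted p = 0.254 with an estimated correlation). Mdm2 went from 439.5 ± 199 to 160.3 ± 42.2 CPM (-1.34, edgeR adjusted p = 3.16e-04). The cell cycle inhibitor Cdkn1a went from 579 ± 225 to 269 ± 48.2 CPM (-1.02, edgeR adjusted p = 0.00115), and Psrc1 (-1.05) and Zmat3 (-0.81) fell too. Of 14 heat shock genes, 10 were lower (12 adjusted over the list alone), Hsph1 by -1.06, with camera adjusted p = 1.21e-17 and adjusted p = 0.254 with an estimated correlation. Of 18 integrated stress response genes, 8 were lower (13 adjusted over the list alone), Ddit3 (-1.28), Trib3 (-0.94), Chac1 (-0.88) and Phgdh (-0.72) among them, with camera adjusted p = 1.56e-11 and adjusted p = 0.269 with an estimated correlation. Of 20 immediate-early genes, 11 were lower, Jun by -0.84, and Egr1 higher, by 0.98 (12 and 1 adjusted over the list alone), with camera adjusted p = 5.14e-07 and adjusted p = 0.254 with an estimated correlation. Of 22 ER chaperones, 3 were lower, Hspa5 by -0.78 (7 adjusted over the list alone, camera adjusted p = 9.85e-05). Of 20 cholesterol genes, 6 were lower and Stard4 higher (11 and 2 adjusted over the list alone, camera adjusted p = 1.69e-04). With an estimated correlation, adjusted p = 0.511 and 0.363 for these lists. Rn7sk was lower in positive cells too. Without the block, camera did not call immediate-early genes without negative replicate 3 (0.133), negative 4 (0.0973) or positive 1 (0.357), nor cholesterol genes without negative replicate 1 (0.0929). With negative replicates 3 and 4 both left out of that fit, chosen after seeing the data, camera still called p53 targets (3.67e-13) and heat shock genes (2.13e-05). It then did not call the integrated stress response (0.0679) or ER chaperones (0.122), and the immediate-early list turned upward (0.930).

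Of 13 alpha cell genes, 7 were higher in positive cells (8 adjusted over the list alone), among them the glutamine transporter Slc38a5, from 291 ± 135 to 587 ± 48.9 CPM (1.13, edgeR adjusted p = 0.0024), Pou3f4 (0.58), Etv1 (0.52) and Slc7a2 (0.48), with camera adjusted p = 1.13e-06 and adjusted p = 0.254 with an estimated correlation. Of 12 beta cell genes, 5 were higher (8 adjusted over the list alone), with G6pc2 (1.17), the channel Trpm5 (1.03) and Bace2 (0.73) beside the insulin genes, and camera adjusted p = 5.04e-09 and adjusted p = 0.254 with an estimated correlation. Of 24 G2 and M phase genes, 4 were higher, such as Aurkb (0.52), Ccna2 (0.44) and Cdk1 (0.42; 10 adjusted over the list alone, camera adjusted p = 9.76e-06). Of 12 mitochondrial transcripts, 2 were higher, mt-Atp6 by 0.68 (6 adjusted over the list alone, camera adjusted p = 6.54e-05). With an estimated correlation, adjusted p = 0.511 and 0.480 for these. The snoRNA host Snhg15 (-1.34; 2 of 12 adjusted over the list alone, camera adjusted p = 0.00727) and the endothelial genes Pecam1 and Tek (-1.60; 2 of 5 adjusted over the list alone, camera adjusted p = 0.00594) were lower. For both lists adjusted p = 0.254 with an estimated correlation. Without the block, camera did not call the mitochondrial list without negative replicate 2 (0.0716) or 4 (0.112) or positive replicate 2 (0.0696) or 3 (0.0866). It did not call the endothelial list without negative replicate 3 (0.133) or 4 (0.0951) or positive replicate 2 (0.0696) or 3 (0.0835), nor with negative replicates 3 and 4 both left out (0.283). The snoRNA host list was not called without the block (0.286). In the blocked fit camera called 12 lists and fry 0 (smallest adjusted p = 0.0762). Without the block camera called 11 lists, 0 with an estimated correlation (smallest adjusted p = 0.0842, 5 at an unadjusted p under 0.05), and fry 6.

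Effects against the empty vector in both experiments were compared over the 17891 genes tested in each. Positive cells and shSmndc1 shared 652 higher genes (104 from independent lists) and 821 lower genes (128), with 0 of opposite sign where 231 would come from independent lists. Negative cells and shSmndc1 shared 346 higher (93.1) and 419 lower genes (81.7), with 1 of opposite sign (176). These 765 genes are not specific to the real groups. When EV_RIP replicates 1, 3 and 4 and negative replicate 1 were set against the other libraries of these groups, 702 genes were shared. Across genes, which are not independent replicates, log2 fold changes in shSmndc1 correlated at 0.76 with those in positive cells and at 0.60 with those in negative cells. Negative and positive cells were both set against EV_RIP, which alone gave correlations between 0.46 and 0.49 in 10 simulations without effects, against 0.79 observed. The covariance was 0.353 observed and 0.0461 simulated, and 0.310 when each group was set against another part of the controls (6 splits, mean correlation 0.64). The sorted libraries are also paired by number, which neither value removes. With the numbers kept apart as well, a test added after seeing the data, the covariance averaged 0.229 over 36 splits (0.130 to 0.275, mean correlation 0.53). These groups shared 702 higher and 704 lower genes. Independent lists give 131 and 96.0, a value that leaves out the shared controls. With the controls split, edgeR called at most 1 gene in negative cells, and 1 gene was shared in 1 of 6 splits. With the numbers kept apart as well, the 36 splits shared on average 5.50 higher and 5.78 lower genes, where independent lists give 1.01 and 1.05, and most of these came from splits that used negative replicates 2 and 4.

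**Figure D3:**
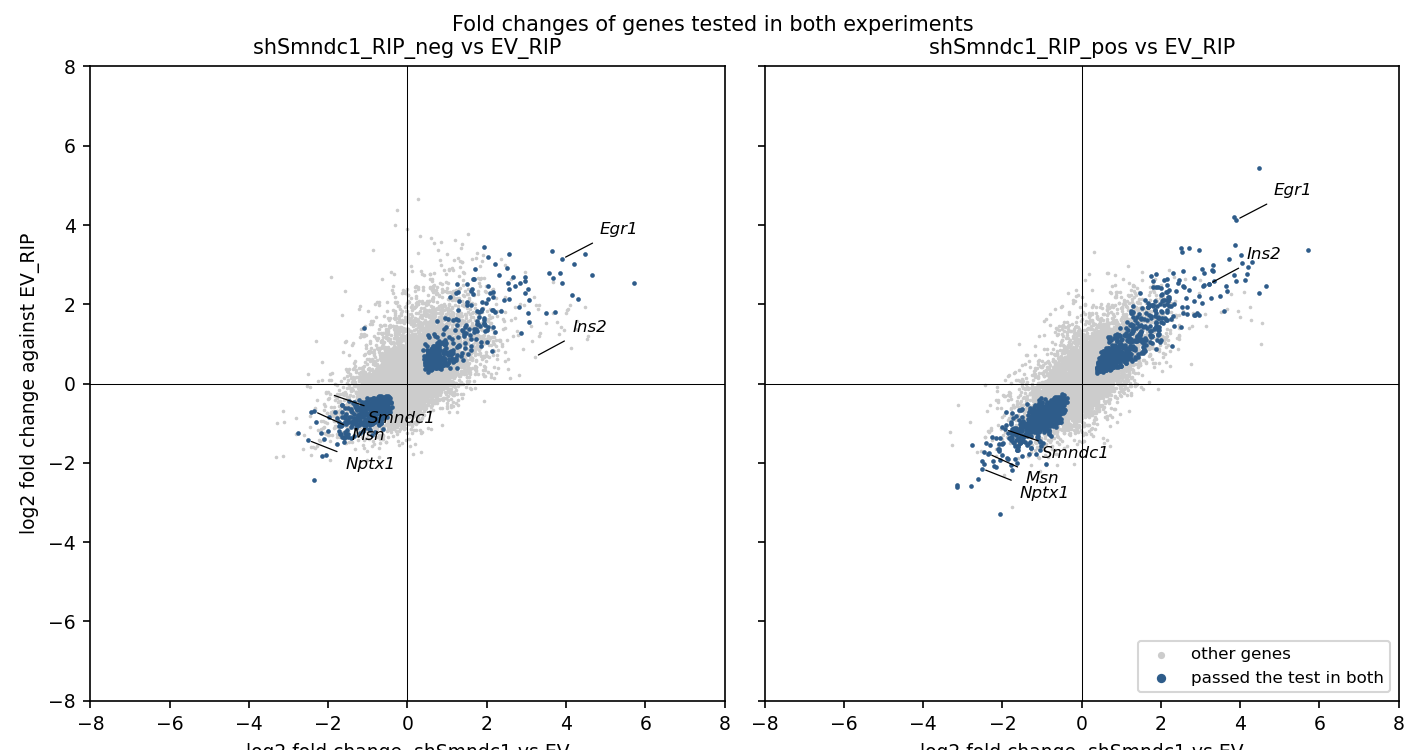
Log2 fold change of each gene in negative or positive cells against EV_RIP (vertical) and in shSmndc1 against EV (horizontal), with genes past the edgeR threshold in both in blue. The points follow the diagonal more closely for positive cells (correlation 0.76 across genes) than for negative cells (0.60).

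The last comparison tests whether the effect of the shRNA groups against their empty vector differs between experiments, as that of experiment 1 minus the mean effect in the sorted groups of experiment 2. EdgeR called 0 of 20036 genes, with 1630 at an unadjusted p under 0.05, while DESeq2 called 23. The genes with the smallest p were the growth factor Vegfa (difference -1.29), Eno3 (1.46), Smndc1 (-1.22), Snord37 (-2.85) and Mtif2 (-0.72), each with edgeR adjusted p = 0.419. Of the fixed genes, Gcg had a difference of 0.16 (0.916) and Atrx of -0.27 (0.792).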

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

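The tests of p53 and heat shock genes, of the depth behind Smndc1 and of immediate-early genes were chosen only after the results were seen, as was the block over the 8 sorted libraries, and the error measures of all tests weighed here replaced earlier ones after first values were seen, because members of a list are not independent replicates.

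Positive and negative cells differed in the paired fit, which called 1517 genes and, by camera with its preset correlation, 12 lists. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.254), and fry called 0 (smallest adjusted p = 0.0762). The genes that differed included Ins2 (log2 difference 1.95) and Ins1 (1.81), for which the reporter selects, and Gcg (0.80) and Smndc1 (-0.86). Of the 8 splits of the paired libraries, 1, the real one, called as many genes, and the highest other split called 0. For lists 1 of 8 reached 12, and the highest other split called 11. These splits are too few for a share under 0.05. The unpaired fit called 0 genes, a number that 35 of 35 splits of the 8 libraries reached, as any split must, so it says nothing about chance. The highest other split called 1048 genes, with negative replicate 1 and positive replicates 1, 2 and 3 against the rest. It points to a structure of the samples: negative replicate 1 stands apart from the other negative libraries, with the lowest Smndc1 (23.9 CPM) and the highest Ins2 (5.13 CPM).

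The p53 targets (median log2 difference -0.76) and heat shock genes (-0.51) were lower in positive than in negative cells. Thinning the 8 libraries to the shallowest left medians of -0.79 (SE 0.23, camera adjusted p = 1.23e-18) and -0.46 (SE 0.13, 1.05e-15). At full depth both lists had adjusted p = 0.254 with an estimated correlation, and fry gave 0.104 and 0.0762, so the list calls rest on the preset correlation. Thinning keeps each gene's expected share of a library, so it can only test effects of low counts on the medians, which it did not find. Other traits of shallow libraries were not tested. Negative cells as a mix of unperturbed and positive-like cells would lie between EV_RIP and positive cells, but they exceeded the higher of those levels by medians of 0.77 (SE 0.25 between libraries, 20 of 23 members) and 0.46 (SE 0.19, 14 of 14). Both lists were picked because they were seen higher in negative cells. The excess thus largely restates that choice and does not exclude a mix. In pairs 1 and 2, whose negative libraries had less Rn7sk (4.45 and 19.4 CPM), the medians were -0.60 for p53 targets (SE 0.475; -0.15 in pair 1, -1.10 in pair 2) and -0.36 for heat shock genes (SE 0.17; -0.23 and -0.56). In pairs 3 and 4 (166 and 48.1 CPM) they were -0.76 and -1.05 for p53 targets and -0.90 and -0.39 for heat shock genes. Heat shock genes differed least in pair 1, with the least Rn7sk, and most in pair 3, with the most, and only pairs 2 and 4 were out of order. The p53 targets also differed least in pair 1, but most in pair 2. With 2 pairs, RNA without a poly(A) tail in negative replicates 3 and 4 cannot be told apart from a difference between the sorted populations, which was not tested.

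Smndc1 was lower in positive than in negative cells. Thinned to the shallowest library, the log2 difference was -0.93 (SE 0.13, edgeR adjusted p = 6.41e-04). Thinning keeps a gene's expected share of a library, so this only shows that low counts do not make the difference. Other traits of shallow libraries were not tested. Negative cells may hold a share of cells without the knockdown, which would shrink every effect by the same share: over 2000 genes called in experiment 1, the effect in negative cells was 0.666 of that in positive cells (SE 0.0875, 0.631 to 0.748 with libraries left out; 0.742 over 1083 lower and 0.532 over 917 higher genes, which differ by 0.211, SE 0.119), and for Smndc1 it was 0.306 (jackknife SE 0.227, 0.132 to 0.412). The ranges do not overlap, which by a bound set before these values were seen would exclude such a mix, but that bound was wrong because leaving out single libraries spans less than the share's own error. Within 2 standard errors the shares cannot be told apart, and a biological difference between the populations stays open.

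Of 21 immediate-early genes, 8 were higher in negative and 7 in positive cells than in EV_RIP, whose labels name no sort. With an estimated correlation camera did not call the list in negative or positive cells (adjusted p = 0.328 and 0.759), and fry did not call it in positive cells (adjusted p = 0.101). If the sort alone raised these genes, none would rise in experiment 1, whose labels name no sort either. But 2 of the 9 members called in a sorted group, Egr1 and Junb, rose there too. There Egr1 went from 2.57 ± 0.420 to 38.2 ± 27.4 CPM (n = 3) and stayed called with any library left out. This argues against the sort as the only cause for Egr1 in positive cells, where Smndc1 fell too. In negative cells a fall of Smndc1 did not pass, so for them the sort as the only cause of the rise in Egr1 stays open. Whether the sort adds to the rise of Egr1 in positive cells stays open. Junb rose by a log2 fold change of 2.56 (SE 0.65), from 8.56 ± 1.78 to 50.7 ± 54.3 CPM. It lost its call with any EV replicate left out (edgeR adjusted p up to 0.119). A call lost with fewer libraries is no sign of the sort, but with this spread the sort stays open for Junb. The other 6 members measured had a median log2 fold change of 0.39 in experiment 1 (SE 0.447), within 1 standard error of 0, so the sort may account for them, as may the knockdown, since the design does not separate the sort from the reporter experiment.

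Single libraries stood far from the rest of their group in 1 group of library measures, 1 of fixed genes, 6 of list means and 8 of named genes, where chance gives about 0.75, 1.25, 3.75 and 5.25. Among library measures, the mitochondrial share was 3.94% in negative replicate 3. Pdx1 had 0.0262 CPM, 1 count, in positive replicate 2. Mean log2 CPM stood apart for alpha cell identity in positive replicate 4 (6.06), chromatin remodelling factors in negative replicate 3 (6.52), snoRNA hosts in negative replicate 1 (4.47), the integrated stress response in positive replicate 2 (4.82), heat shock genes in EV_RIP replicate 4 (7.37) and leukocyte and macrophage markers in positive replicate 3 (0.95). Among named genes, EV_RIP replicate 4 held 171 CPM of Gjd2, 102 CPM of Hsd11b1, 38.9 CPM of Lsamp and 16.9 CPM of Gpr142. Btbd17 had 40.5 CPM in EV_RIP replicate 1, Gjd2 63.3 CPM in positive replicate 1, Lsamp 26.3 CPM in negative replicate 3 and Rph3a 8.40 CPM in negative replicate 1.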

How the results depend on the processing

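Thinning, the block over the 8 sorted libraries with or without pair 3, and leaving out negative replicates 3 and 4 were tests chosen only after the results were seen. Of 7698 alternative values of named genes, 6742 stayed on their side of the threshold, including 62 uncalled values that changed sign. Of the rest, 609 lost their call, 347 gained one and 0 reversed. Of 1350 alternative values of lists, 1235 stayed on theirs, 70 lost their call, 44 gained one and 1 reversed: the immediate-early list in positive against negative cells turned upward with negative replicates 3 and 4 left out (camera adjusted p = 0.930). The cause of a change was not tested unless its construction gives it, as a fold minimum, fewer genes or fewer libraries do.

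A fold minimum of 2 left 506 higher and 499 lower genes in shSmndc1, 927 and 101 in negative and 753 and 284 in positive cells. Without a filter, 2024 and 2141 genes were called in shSmndc1, 1700 lower in negative cells, 39 and 111 between positive and negative cells and 30 for the difference between experiments. DESeq2 called 2435 higher in negative cells, 110 and 205 between the sorted groups and 23 for the difference. Limma on FPKM called 994 higher in negative cells, and with only the compared groups edgeR called 843 and 446 there. Thinned to the shallowest library, 714 genes were lower in negative and 1086 in positive cells, so depth limits these counts. With negative replicates 3 and 4 left out, 4 genes were higher in negative cells and 0 lower.

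All replicate numbers pair the sorted groups, while the other groups pair only in part. EV and shSmndc1 correlated at -0.03, -0.01 and 0.26 (own number highest in 1 of 3), and EV_RIP with negative cells at 0.28, 0.49, -0.20 and -0.29 and with positive cells at 0.26, 0.43, -0.03 and -0.05 (2 of 4 each, numbers 1 and 2). With the block over 12 libraries, edgeR called 2421 higher and 2176 lower genes in negative cells, 2508 and 2571 in positive cells, and 22 and 56 between them. It also took the call from the interferon and ER chaperone lists in negative cells (camera adjusted p = 0.0536 for both), and gave one to Ins1 in negative cells (0.0372). In experiment 1 a block over its 6 libraries took the call from Atrx (adjusted p = 0.0573). Over the 8 sorted libraries the block called 667 and 850, or 462 and 616 with pair 3 left out. Smndc1 in positive against negative cells passed without a filter (-0.87, adjusted p = 0.0158), by DESeq2 (-0.88, 0.0104), with the block over 12 (-0.87, 0.0346) or 8 libraries (-0.86, 9.54e-04), and with pair 3 left out (-0.77, 0.00327).

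With single libraries left out, higher and lower genes ranged from 71 to 1547 and 110 to 1789 in shSmndc1, 127 to 3036 and 32 to 2795 in negative cells, and 646 to 1811 and 612 to 1775 in positive cells. Between the sorted groups they ranged from 0 to 220 and 0 to 297 (2 and 3 without positive replicate 4), and the difference between experiments stayed at 0. Log2 fold changes of Smndc1 ranged from -2.02 to -1.90 in shSmndc1, -0.37 to -0.10 in negative cells, -1.29 to -1.02 in positive cells and -1.04 to -0.78 between them. Lists called numbered 0 to 4, 7 to 10, 4 to 6 and 8 to 12 in these comparisons. In shSmndc1, fry called 1 list, camera 4 without a filter and 2 with the block. An estimated correlation left 0 lists in every comparison and in the blocked fit, and fry called 10 in negative cells, 1 in positive cells and 6 between the sorted groups. Genes shared with experiment 1 numbered 461 for negative cells with only the compared groups, 158 and 383 for negative and positive cells at a fold minimum of 2, and 432 for the blocked difference.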

Other observations

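The Zscan4, 2-cell and clock genes below were chosen after values of Zscan4, Nr1d1 and Ciart had been seen, and the tests of the other members were written before those members were looked up, except the count of 2-cell genes that pass the filter on EV alone, a test chosen only after the results were seen.

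In shSmndc1 all 6 Zscan4 genes, known from the 2-cell embryo, rose, by log2 fold changes of 3.25 (Zscan4e) to 4.56 (Zscan4f), and Zscan4b went from 0.364 ± 0.155 to 6.83 ± 0.941 CPM (log2 fold change 4.24, SE 0.32, adjusted p = 0.00145). Summed over the family, the mean was 1.65 ± 1.19 CPM in EV and 26.5 ± 7.24 CPM in shSmndc1. The hypothesis that other genes of the 2-cell embryo rise along was put to 23 listed genes, of which 10 were missing from the table or had too few counts to be tested. Of the 13 measured 11 (84.6%) rose, but 10 of the 13 pass the expression filter only with the shSmndc1 libraries, so they were measured because they rose and the share decides nothing. Of the 3 that pass on EV alone, 1 rose. The 11 were 5 Usp17l genes (Usp17ld 3.99), Tcstv1 (3.95), Tcstv3 (3.24), Duxf3 (3.27), Zfp352 (2.97), Pramef25 (2.95) and Pramef8 (0.60, from 41.3 to 62.5 CPM), but not Zfp809 (-0.29, 0.312) or Arg2 (0.01, 0.982). A 2-cell-like program cannot be told apart from a rise of single families. Most members had under 1 CPM in EV, and members of a family share sequence, so the 13 genes are not 13 independent tests. With EV replicate 3 left out, 3 of 16 measured 2-cell genes and 4 of 6 Zscan4 genes were called higher, with 15 and 6 above 0.

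In the sorted groups the family sum was 1.45 ± 0.889 CPM in EV_RIP, 3.40 ± 4.30 in negative and 4.71 ± 1.29 in positive cells. None of the 6 Zscan4 genes rose in negative cells (median log2 fold change 1.46) and 1 did in positive cells (median 1.77; Zscan4e 2.16, adjusted p = 0.0466). Of 7 other 2-cell genes measured, 2 rose in each group, Pramef8 (0.46 and 0.62) and Pramef25 (2.69 and 3.36). The difference between experiments was 2.59 for Zscan4b (SE 0.86, adjusted p = 0.497), so a larger effect in experiment 1 is not shown.

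The clock repressor Nr1d1 rose in shSmndc1 (1.25, adjusted p = 0.0197), in negative cells (2.50, 0.00740) and in positive cells (1.78, 0.00853). Ciart rose in the sorted groups (2.39 and 1.94), with a log2 fold change of 0.27 in shSmndc1 (0.527). If the clock stood at another phase in the sorted cells, most other E-box genes would rise in positive cells and genes of the opposite phase fall. Of 12 E-box genes 2 rose there (16.7%), Per1 (0.62, 0.0306) and Bhlhe41 (1.44, 0.00188), Hlf fell (-0.74, 0.0218), and 0 of 3 measured genes of the opposite phase fell. A shift of phase cannot be told apart from an effect on single genes, and the time of collection is not given.

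Smndc1 takes part in splicing, so genes with more introns might fall more after its knockdown. Spearman's rho between intron number and log2 fold change was -0.00899 over 11773 genes in experiment 1 and 0.0474 in positive cells, neither below the -0.1 set for that hypothesis. In negative cells rho was 0.111, opposite in sign to the hypothesis. The 238 intronless genes of experiment 1 had a median of 0.00 and the 1503 genes with over 20 introns one of 0.01. Of the genes with over 20 introns 10.9% were called lower and 7.65% higher in experiment 1, and of the intronless genes 4.20% and 5.04%. The balance for genes with over 20 introns was reversed in the sorted groups. There 2.84% were lower and 13.2% higher in negative cells, and 9.13% and 11.9% in positive cells. Intronless genes had 4.45% and 7.69% in negative cells, and 6.67% each way in positive cells. Why these shares differ was not tested. Counts per gene do not show how transcripts were spliced.

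Libraries were also divided into groups of the real sizes in every other way, and each division was fitted as the real one. In experiment 1 the real division called 2681 genes and the highest other 0, so 1 of 10 called as many, and these divisions are too few for a share under 0.05. For lists 10 of 10 reached the real count of 0, as any division must (highest other 10). Positive cells against EV_RIP gave 3286 genes, reached by 1 of 35 (highest other 0). By the rule set in advance this excludes chance for that count, without adjustment for the number of such tests. It is the smallest share that 35 divisions can give. Every other division mixes the groups, so the result does not separate the knockdown from the sort or the reporter. Positive cells gave 1473 genes shared with experiment 1, also reached by 1 of 35 (highest other 0). A division that calls 0 genes shares 0, so the sharing is no separate test. For the 5 lists of positive cells 20 of 35 reached as many (highest other 8), and chance cannot be excluded.

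Negative cells against EV_RIP gave 2620 genes, and 2 of 35 divisions called as many. The highest other called 3259, with EV_RIP replicates 1, 3 and 4 and negative replicate 1 against EV_RIP replicate 2 and negative replicates 2, 3 and 4. Chance cannot be excluded for the count, and that division points to a structure of the samples. The 8 lists were reached by 14 of 35 (highest other 13). The 765 genes shared with experiment 1 were reached by 1 of 35, with 702 in the highest other. By the rule set in advance this excludes chance, by a small margin. But a division that calls 0 genes shares 0, so the sharing repeats the test of the calls and decides nothing of its own. Between positive and negative cells without pairing, 5 of 35 reached the 11 lists called (highest other 12). For the difference between experiments all 40 divisions, the real one and random ones, reached its 0 genes, as any must (highest other 1261). That count of 0 says nothing about chance. Of the 1261 genes, 1164 were called with the same sign in shSmndc1 against EV. That division thus mostly repeats the calls of experiment 1 and does not point to another structure of the samples.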
